A study of Drosophila melanogaster with 6 samples.

How the data were processed

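The data are CUT&RUN libraries, in which an antibody directs a protein A/G-micrococcal nuclease fusion to cut and release the chromatin around a histone mark, from wing imaginal discs of Drosophila melanogaster. The discs, the larval precursors of the adult wing and thorax, expressed either histone H3 in which lysine 27 was replaced by methionine (H3K27M, an oncohistone) or by arginine (H3K27R, the control). Per the labels, each genotype had 2 libraries for trimethylated H3 lysine 27 (H3K27me3), the mark written by Polycomb repressive complex 2, and 1 library with a non-specific IgG. The transgenes were driven by Act5C-GAL4 and held off by a temperature-sensitive GAL80 until larvae were moved from 25 °C to 32 °C at 44 h after egg laying, and were then expressed for 72 h. Larvae were staged to 116 to 119 h, and 20 discs were dissected per replicate. Barcoded nucleosomes diluted 1:100 were added as a spike-in, per the labels' protocols.

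Of the processed data, 2 files were analysed here. The first is the authors' list of broad H3K27me3 peaks, and the labels attach this 1 list to both H3K27R H3K27me3 libraries, so it holds no value per replicate. Per the file layout, which has no header, it gives each peak's start and end, a score, the authors' fold enrichment over the peak caller's background, and the authors' −log10 p-value and −log10 q-value. The deposited score was the integer part of 10 times the −log10 q-value in 100% of peaks and was not used further. Bowtie2 and MACS2 and the genome build dm6 are named in the submitters' processing notes. Versions, the peak threshold and whether the IgG libraries served as the background are not given in the sources used here. The smallest deposited −log10 q-value was 1.05, and the smallest fold enrichment was 1.73. The second file is the authors' list of genes upregulated with H3K27M, as 148 intervals with a strand. It holds no gene names and no expression values, and how the genes were called, on which RNA libraries, and against which group are not given in the sources used here. H3K27me3 signal tracks and H3K27M peaks were not analysed here, so no change of H3K27me3 between the genotypes is reported.

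Genes were taken from a RefSeq gene table of Drosophila assembly Release 6, the assembly that dm6 names. All 148 deposited intervals equalled the span of exactly 1 gene of this table, to the base, and took that gene's symbol. The analysis was limited to the 6 chromosome arms that carried peaks (X, 2L, 2R, 3L, 3R and 4), with 17673 annotated genes, of which 13911 were protein-coding. The arm length was set to the end of its last annotated gene. Coordinates are 1-based. A gene was counted as overlapping a peak when at least 1 bp of its span did. Domains are peaks merged across gaps of up to 5000 bp. The file gives 1 fold enrichment per peak, and a domain was given the highest value of its peaks. The gene table gives no strand, so transcription start sites were not used for genes outside the deposited list.

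Shares of genes were compared with Fisher's exact test (two-sided), with conditional odds ratios and exact 95% intervals, and shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Because long genes overlap any interval more often, the upregulated genes were also set against 10000 random gene sets matched on chromosome arm and on 10 classes of gene length. Means and medians were compared with two-sided permutation tests of 100000 resamples (10000 for the unplanned tests of gene length and of distance to a peak), with bootstrap 95% intervals from 2000 resamples. Neighbouring upregulated genes were counted in the order of protein-coding genes and compared, one-sided, with 10000 random sets drawn within each arm. The 7 planned tests of the upregulated list were adjusted together by Benjamini-Hochberg. The 20 gene lists, written before the data were examined, were tested with Fisher's exact test and adjusted over the 20 lists, separately for overlap with peaks and for membership in the upregulated list. All 312 list entries matched a gene, 4 of them by locus tag because the symbol was ambiguous or absent. These p-values treat genes as independent, which neighbouring genes under 1 domain are not, and none of them measures the spread between biological replicates, since neither file holds replicates. Library depth is unknown.

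The genes named were chosen by a rule fixed at the same time. They are all listed genes of the fixed lists that were upregulated; the 15 upregulated genes over peaks with the highest covered share; the 5 nearest to and the 5 farthest from a peak among upregulated genes without one; the 10 highest peaks and the 10 widest domains; and, as groups, Hox, Polycomb group and housekeeping genes. Peaks and domains are named by the fixed-list genes they hold, or else by the overlapping gene with the longest covered length. Other genes of the lists serve as examples and were chosen after their values were seen.

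The tests were checked on simulated data. Gene sets of 131 drawn from the 13911 genes with a planted odds ratio of 2, 3 or 4 for overlap with a peak were called in 71.8%, 98.6% and 100% of 500 draws, and with a planted odds ratio of 1 in 4.4%. Sets drawn to favour long genes, without regard to peaks, were called in 35% of 200 draws by Fisher's exact test and in 3% by the length-matched test. The strength of that length bias was not fitted to the upregulated list, so 35% is not the rate for these data. All sets were drawn gene by gene, without the runs of neighbours that the real list holds. Alternatives covered the overlap that counts, stricter peaks, merging, the background genes, collapsing of domains, and the matching. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.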

Results

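H3K27me3 was profiled by CUT&RUN in wing imaginal discs expressing H3K27M or the H3K27R control, with 2 H3K27me3 libraries and 1 IgG library per genotype, 6 libraries in all. The data analysed were the authors' list of H3K27me3 peaks in H3K27R discs, 1 list that the labels attach to both replicates, and the authors' list of genes upregulated with H3K27M. The comparison these lists allow is whether the genes upregulated by the oncohistone lay where the mark was found in control discs. Neither list carries replicate values or read depth, so the intervals given cover counting error over genes or peaks only.

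In control discs, H3K27me3 lay in broad blocks, the widest of them over developmental regulators, and in many small, weak patches. The list held 1709 peaks covering 9.86 Mb, or 7.38% of the 133.6 Mb up to the last gene of each arm. Most peaks were small: the median width was 1058 bp, and 824 peaks were under 1 kb. The 225 peaks of at least 10 kb held 77.0% of the covered length. The authors' fold enrichment had a median of 2.39 and a maximum of 21.9. The 284 peaks with a −log10 q-value of at least 10 made up 16.6% of peaks but 76.4% of the covered length, with a median width of 18979 bp against 822 bp for the other peaks. Across peaks, wider peaks had higher fold enrichment (Spearman rho 0.63; peaks are not independent replicates). The covered share was 14.1% on chromosome 4, 9.50% on 2L, 8.42% on 3R, 6.55% on 2R, 6.26% on X and 5.81% on 3L. Merging across gaps of up to 5000 bp gave 748 domains.

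Most of the widest domains and highest peaks held genes of transcription factors, and the exceptions were a peak over a microRNA gene and a domain over FGF ligand genes. The widest domain, 215.3 kb at 3R 16762493 to 16977777, covered abd-A and Abd-B, the Hox genes of the abdomen. It was followed by a 214.3 kb domain over tsh, a trunk and proximal appendage factor (2L 21766935 to 21981190), and by 193.5 kb over the Iroquois genes ara, caup and mirr (3L 12539011 to 12732499). The spalt genes salm and salr lay in 187.0 kb, ct in 167.2 kb, bi in 156.6 kb, the T-box genes H15 and mid in 150.8 kb, SoxN in 145.6 kb, the FGF ligand genes pyr and ths in 129.9 kb, and ems in 122.0 kb. Several domains also held protein-coding genes not named here: that over SoxN held 14 in all, and those over tsh and ems 9 each. These widest domains were not the highest: the domain over tsh reached a fold enrichment of 5.47, and the domain over abd-A and Abd-B 15.0. The highest peak, at 21.9-fold, was only 939 bp wide (2R 8014785 to 8015723) and overlapped no protein-coding gene but held the microRNA gene mir-4981. The next were over the caudal gene cad (20.2-fold, 2L 20767218 to 20787310), eve (19.3-fold), the paired-type genes gsb and gsb-n (16.9-fold), Pph13 (16.5-fold), Dfd (16.4-fold), pnr (16.3-fold), rib (16.2-fold), croc (16.2-fold) and Sox100B (16.1-fold).

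Among 20 gene lists fixed beforehand, 10 overlapped peaks more often than other protein-coding genes after adjustment over the lists (Fisher's exact test, adjusted p at most 0.030). Of all 13911 protein-coding genes, 1005 (7.22%) overlapped a peak. All 8 Hox genes did (95% interval 63.1 to 100%; Fisher's exact test, adjusted p = 2.1e-09), in 6 domains, and 7 of them were covered over at least 50% of their span. Ubx, abd-A, Abd-B, Dfd and lab were covered over 100%, whereas Antp, the Hox gene of the second thoracic segment, was covered over 39.8%. All 18 eye and antenna determination genes overlapped a peak (Fisher's exact test, adjusted p = 2.5e-20), among them eya, ey, toy, so and dac. So did 28 of 30 wing disc patterning genes (Fisher's exact test, adjusted p = 5.9e-29), among them vg, nub, wg, dpp, en and Dll, while fng and sd had no peak. The share was 17 of 20 for mesoderm and muscle factors (Fisher's exact test, adjusted p = 1.6e-16), 17 of 22 for segmentation genes (2.6e-15), 22 of 29 for neural fate factors (4.0e-19), and 16 of 22 for secreted signalling ligands (8.1e-14), which included all of upd1, upd2 and upd3, the ligands of the JAK/STAT pathway. Several of these lists share genes.

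Most lists of genes of other kinds did not pass the threshold for overlap with peaks. Of 20 Polycomb group genes, 3 overlapped a peak: Su(z)2 (92.9% covered, 7.06-fold) and Psc (72.4%, 4.24-fold), the adjacent genes of a Polycomb repressive complex 1 subunit and its relative, and ph-p (1.5%, 2.09-fold). The share did not pass the threshold (Fisher's exact test, adjusted p = 0.29). Of 15 housekeeping genes, 2 overlapped a peak, alphaTub84B over 348 bp and eEF1alpha1 over 340 bp (Fisher's exact test, adjusted p = 0.42). None of 11 cell cycle genes and none of 8 cell death genes overlapped a peak, which allows shares of up to 28.5% and 36.9%. A single gene did so among 15 E(spl) and Brd complex genes (E(spl)m5-HLH), 16 heat shock and stress genes (Ets21C), 13 antimicrobial peptide and immune genes (Def) and 9 haemocyte markers (srp), and Or42b and Or85a did among 13 chemosensory receptor genes (Fisher's exact test, adjusted p at least 0.37). Of 16 germline genes, vas, mael and dhd overlapped a peak (Fisher's exact test, adjusted p = 0.19). Testis genes passed the threshold with 4 of 14 (comr, can, dj and fzo; Fisher's exact test, adjusted p = 0.030), but not with peaks at or above the median fold enrichment (3 of 14, adjusted p = 0.067). Among markers of cells that accompany the disc epithelium, 4 of 8 adult muscle precursor markers (twi, htl, zfh1 and ct; Fisher's exact test, adjusted p = 0.0033) and 4 of 5 tracheal markers (trh, vvl, kni and dysf; adjusted p = 0.00032) overlapped peaks.

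**Figure D1:**
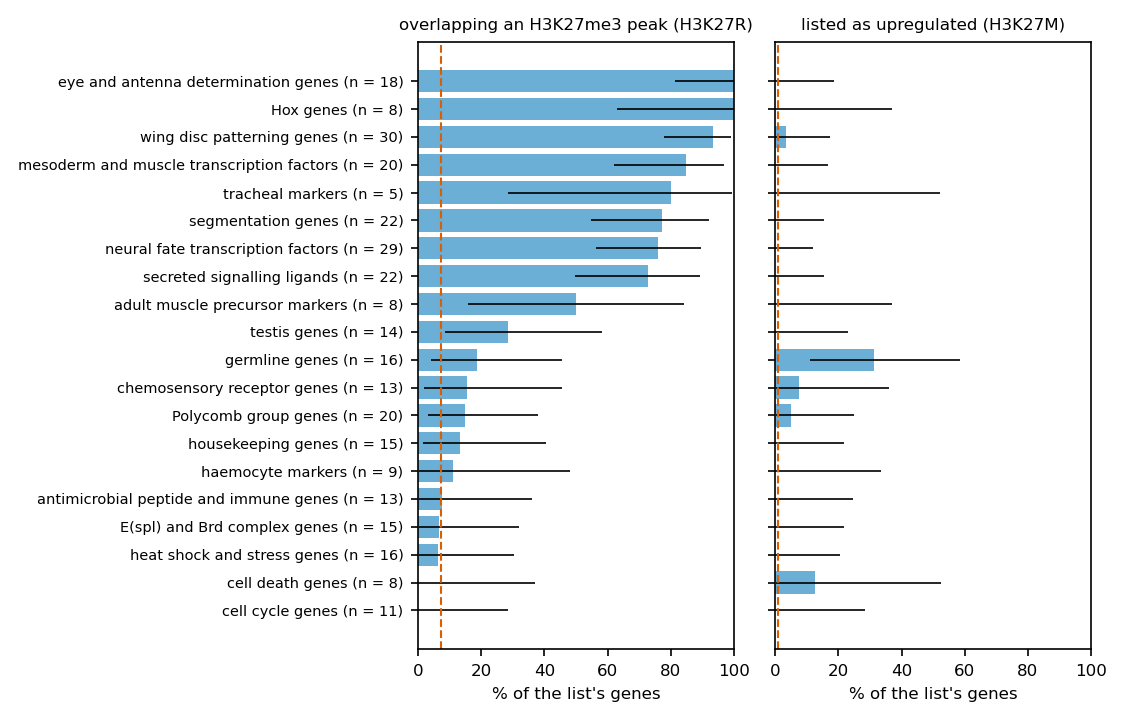
Share of the genes of each fixed list that overlapped an H3K27me3 peak of H3K27R discs (left) and that were listed as upregulated with H3K27M (right), in percent of the list's genes. Bars are shares, black lines are exact 95% intervals, and the dashed line is the share of all protein-coding genes (7.22% and 0.94%). Germline genes stand at 31.3% on the right.

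Few of these regulators were on the list of genes upregulated with H3K27M, a list that held 0.94% of all protein-coding genes. The authors' list held 148 genes, of which 131 were protein-coding, 11 were long non-coding RNA genes, 2 were antisense RNA genes, and the others were pseudogenes or a signal recognition particle RNA gene. None of the 8 Hox genes, the 18 eye and antenna genes, the 22 segmentation genes, the 29 neural fate factors, the 20 mesoderm and muscle factors or the 22 ligand genes was listed. These lists held 115 different genes, of which 1.08 would be listed at the share of all genes, so a lower share among them was not detectable. Of the 297 different genes on the fixed lists, 138 overlapped a peak, and 2 of these (1.45%) were listed as upregulated: zfh2, a zinc finger homeodomain factor of the proximal wing (chromosome 4, 501810 to 540874, 40.9% covered, 4.72-fold), and Psc. Over all protein-coding genes, 1.49% of those with a peak and 0.90% of those without one were listed.

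Germline genes were the one fixed list whose share of upregulated genes passed the threshold. Of its 16 genes, 5 were listed (31.3%, 95% interval 11.0 to 58.7%) against 0.94% of all protein-coding genes, with an odds ratio of 49.6 (13.3 to 157.5; Fisher's exact test, adjusted p = 5.5e-06 over the 20 lists). They were piwi and krimp, which act in the piRNA pathway that silences transposons, nanos, a translational repressor of germ cells, bam, a differentiation factor of germline stem cells, and zpg, a germline gap junction protein. None of these 5 overlapped a peak, and their distances to the nearest peak ran from 28.6 kb to 111.2 kb. The other 11, among them vas, aub, osk and AGO3, were not listed. No testis gene of 14 was listed, which allows up to 23.2%. Single members of other lists were Gr64f, a sugar taste receptor, skl, a pro-apoptotic gene, zfh2 and Psc, and the shares of those lists, 3.33% to 12.5%, were above that of all genes but did not pass the threshold (Fisher's exact test, adjusted p at least 0.73). No haemocyte, adult muscle precursor or tracheal marker was listed.

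The overlap of upregulated genes with H3K27me3 peaks could not be distinguished from that of other genes when each gene was counted. Of the 131 protein-coding upregulated genes, 15 (11.5%, 6.55 to 18.2%) overlapped a peak, compared with 990 of 13780 other genes (7.18%, 6.76 to 7.63%). The odds ratio was 1.67 (0.90 to 2.88), and the difference was not significant (Fisher's exact test, p = 0.086, adjusted p = 0.30 over 7 tests). Upregulated genes were longer than other genes, with a median span of 3350 bp against 2158 bp (permutation test on log10 length, p = 0.0004, not planned). Random sets matched on length and arm overlapped peaks in 9.12% of their genes, and the observed number was 1.26 times their mean (permutation p = 0.40, adjusted p = 0.84). The other 116 genes (88.5%) had no peak, and none of the 17 upregulated genes that do not encode proteins had one. The direction of the difference depended on what counts as overlap, and the call on how neighbouring genes were counted. At least 50% of the gene span was covered in 3 of 131 upregulated genes and in 560 of 13780 others (odds ratio 0.55, 0.11 to 1.66, Fisher's exact test, p = 0.50), and 3 against 474 overlapped a peak with a −log10 q-value of at least 10 (odds ratio 0.66, 0.13 to 1.98, p = 0.63). With 1 gene kept per domain or run, 15 of 115 upregulated and 500 of 13273 other genes overlapped a peak (odds ratio 3.83, 2.05 to 6.69, Fisher's exact test, p = 3.4e-05). That count removes other genes that share a domain and none of the 15. Outside domains it collapses only runs of upregulated genes, so both steps raise the odds ratio.

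**Figure D2:**
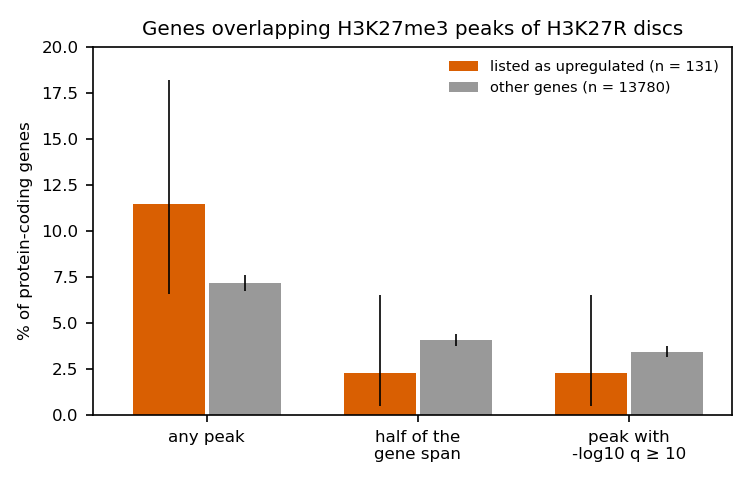
Percent of protein-coding genes listed as upregulated with H3K27M (orange, n = 131) and of all other protein-coding genes (grey, n = 13780) that overlapped H3K27me3 peaks of H3K27R discs, by any overlap, over at least 50% of the gene span, and with peaks of −log10 q-value of at least 10. Lines are exact 95% intervals; the upregulated share is 11.5% against 7.18% for any overlap and 2.29% against 4.06% and 3.44% for the stricter ones.

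Where upregulated genes met a peak, the peak was mostly weak and covered part of the gene. CG13287 (3L 5882304 to 5884090, 2.78-fold) and bard (3R 18081048 to 18082583, 3.14-fold) were covered over 100% of their span. They were followed by Psc (2R 12965997 to 12980994), rhi, the HP1-family protein of piRNA clusters (48.0%, 2.23-fold), yellow-e (44.5%, 2.54-fold), zfh2, Kots (35.5%, 2.22-fold), cona, a synaptonemal complex gene (23.6%, 2.31-fold), mwh, a wing hair polarity gene (19.0%, 3.48-fold), and Hsc70-2 (11.6%, 2.43-fold). CG2901 was covered over 7.91%, and CG14082, hiw, CG42260 and dpy, a wing cuticle matrix gene, over less than 4%. Of the 15, 3 overlapped a peak with a −log10 q-value of at least 10 (Psc, zfh2 and mwh), and 4 had their start site in a peak. The other 12 (80%) met only weaker peaks, compared with 516 of 990 other genes with a peak (52.1%; odds ratio 3.67, 0.98 to 20.4; Fisher's exact test, p = 0.037, neither planned nor adjusted). Weaker refers here to the called peak and not to the merged domain around it. The peak over Kots lay at the end of the 122.0 kb domain over ems, whose highest peak stood at 7.96-fold. Among genes with a peak, the covered share was 33.9% ± 34.1 (SD, n = 15 genes) for upregulated genes and 58.9% ± 40.2 (SD, n = 990 genes) for others, a difference of −24.9 percentage points (permutation test, p = 0.017, not adjusted). Neither comparison among genes with a peak was matched on gene length. The least covered genes, dpy, CG42260, hiw and CG14082, were long, with spans of 33595 to 136839 bp, so length may account for the difference. Over all genes the mean covered share was 3.89% for upregulated and 4.23% for other genes, a difference of −0.34 percentage points (−2.84 to 2.62; permutation p = 0.84, adjusted p = 0.84).

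No difference in the median fold enrichment of peaks or the median width of domains was detected. The 24 peaks over upregulated genes had a median fold enrichment of 2.34, and the 1080 peaks over other genes 2.42 (difference −0.07, −0.21 to 0.14; permutation p = 0.53, adjusted p = 0.84). The 17 domains over upregulated genes had a median width of 3373 bp and the 569 over other genes 4642 bp (difference in log10 width −0.14, −0.79 to 0.74; permutation p = 0.74, adjusted p = 0.84). Protein-coding upregulated genes without a peak lay a median of 113.6 kb from the nearest one, and other genes without a peak 75.6 kb (permutation test on log10 distance, p = 0.0053, a test not planned). Of all 148 listed genes, the nearest without a peak were CG3556 at 1404 bp, CG1628 at 1854 bp, slam at 2809 bp, the signal recognition particle RNA gene 7SLRNA:CR42652 at 2890 bp and CG11594 at 2990 bp. The farthest were CG40439 at 763626 bp, the ribosomal RNA pseudogene 28SrRNA-Psi:CR41609 at 620977 bp, lncRNA:CR46472 at 448412 bp, HP1D3csd at 341105 bp and lncRNA:CR46007 at 319448 bp.

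**Figure D3:**
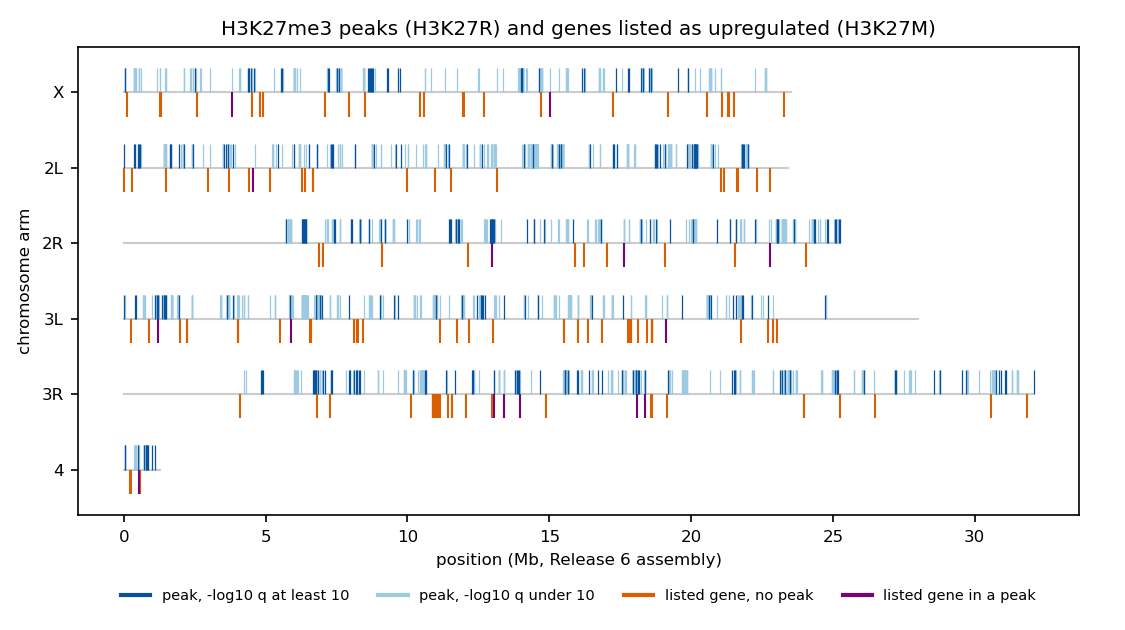
Positions along the 6 chromosome arms (Mb) of H3K27me3 peaks in H3K27R discs (blue, above each line; dark for −log10 q-value of at least 10) and of the 148 genes listed as upregulated with H3K27M (below each line; orange without a peak, purple over a peak). The 15 genes over peaks are spread over all arms, and a dense block of genes without peaks stands on 3R.

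Upregulated genes lay side by side more often than in random gene sets, and no enrichment on the X chromosome was detected. The X held 22 of 131 upregulated genes (16.8%) and 2170 of 13780 others (15.7%; odds ratio 1.08, 0.65 to 1.72; Fisher's exact test, p = 0.72, adjusted p = 0.84). The arms as a whole differed (permutation test, p = 0.00016, chosen after the values were seen), with 42 of 2739 genes listed on 3L, 12 of 2849 on 2R and 4 of 80 on chromosome 4. In the order of protein-coding genes, 16 pairs of neighbours were both listed, against a mean of 1.46 and a highest value of 7 in 10000 random sets (permutation test, p = 1e-04, the smallest they can give; adjusted p = 0.0007). The 7 runs held 23 genes. The longest were CG6621, Tengl4, side-VI, CG43449, SdhCL, Ugt35C1 and mAcon2 on 3R (10889768 to 11139742) and CG18234, CG18233, CG18231, CG32201 and CG32199 on 3L (18603425 to 18614004). No gene of any run overlapped an H3K27me3 peak. Without the run on 3R, 10 pairs remained against a mean of 1.35 (permutation test, p = 1e-04, again the smallest possible). The genes of the run on 3L are adjacent. Whether they are related in sequence was not tested, and how reads shared between genes were counted is not given in the sources used here.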

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

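No paired analysis was possible because neither file holds a value per replicate, and for the same reason no replicate could be left out. Counting transcription start sites in peaks was not run for want of strands outside the deposited list; either end of the gene span was used in its place, an alternative added after seeing the data, as was leaving out the genes of the 3R run or genes that overlap another listed gene. The odds ratio for upregulated genes in peaks (1.67) fell below 1 with at least 50% of the span covered (0.55), with peaks of −log10 q-value of at least 10 (0.66) and with either gene end in a peak (0.82), and none of these passed the threshold; the cause was not tested. It passed only with genes collapsed to 1 per domain or run (3.83, Fisher's exact test, p = 3.4e-05). This took the other genes in domains from 1007 to 500, while all 15 upregulated ones stayed because none shared a domain with another. Outside domains only runs of upregulated genes were collapsed, which took the upregulated genes from 131 to 115. Both steps raise the odds ratio. The 6 other alternatives gave 1.34 to 1.78 (p at least 0.052). The difference in covered share (−0.34 points) grew to −24.9 among genes with a peak, and passed the threshold there. By construction this leaves out the genes at 0, and it was not matched on gene length. The fold difference of peaks turned from −0.07 to 0.051 with merged domains, and the log10 width difference from −0.14 to 0.0075, 0.093 and 0.098 with gaps of 0, 1000 and 10000 bp; none passed the threshold, and the cause was not tested. The 1709 peaks became 855 at or above the median fold enrichment and 748 merged domains, while the covered length stayed at 9.12 to 11.6 Mb. The germline enrichment fell to 0 of 3 genes (odds ratio 0, and 0 lists past the threshold by Fisher's exact test) when only genes over peaks were considered, since none of the 5 has a peak. The count of gene lists over peaks was 9 and 10 under its alternatives. Of 53 alternatives, 39 were classed as unchanged. For tests this means the same direction and side of the threshold, and for counts and covered lengths a value close to the main one. Many of the 39 were single gene lists over peaks that had passed the threshold in the main setting. The excess of neighbouring upregulated genes held in its 3 alternatives (3.47 to 9.20 times the mean of random sets). Depth is unknown, so H3K27me3 under the authors' peak threshold is not detectable here.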

Other observations

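The tests of wing domains, weak peaks, distance to peaks, runs and the 3R region, and the peak and testis counts for the germline pattern, were chosen after the results were seen; the germline enrichment itself comes from the lists fixed beforehand.

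H3K27me3 over the listed wing disc patterning genes was lower at the median than over genes of the Hox, segmentation, eye, neural and mesoderm lists. Those lists do not stand for other tissues alone. They hold Antp, of the second thoracic segment, and the adult muscle precursor markers twi and zfh1. The wing list also holds ligand genes such as wg and dpp, so tissue and kind of gene cannot be told apart. The 24 domains over wing disc patterning genes reached a median fold enrichment of 6.57 (quartiles 5.15 and 9.21), and the 58 domains over Hox, segmentation, eye, neural and mesoderm factors without a wing gene reached 10.3 (7.63 and 13.3). The difference was −3.75 (−5.69 to −1.05; permutation test over domains, p = 0.0027). Among wing genes, vg stood at 4.90-fold, salm at 4.83-fold, ptc at 4.18-fold and bi at 5.22-fold, whereas eve stood at 19.3-fold, Optix at 13.7-fold, ey at 13.4-fold and abd-A at 15.0-fold. The groups overlapped: 4 of the 24 wing domains lay above the median of the others, and 11 of the 58 others lay below the wing median. Among the wing genes pnr stood at 16.3-fold, dve at 12.7-fold and Dll at 12.4-fold. Among the others vnd stood at 2.3-fold, sna at 2.51-fold, ac at 2.90-fold, sc at 3.08-fold, run at 3.14-fold, twi at 3.40-fold and slou at 3.94-fold. The genes named here were chosen after their values were seen. Domain widths were 62.6 kb and 49.6 kb at the median (permutation test, p = 0.32). Beyond the 5 germline genes of the fixed list, the upregulated list also held rhi, del, qin, BoYb and SoYb, which act in the piRNA pathway, and tut, a partner of bam; these were picked after the list was seen and were not tested.

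Of the protein-coding upregulated genes, 88.5% lay outside H3K27me3 peaks, and so did 92.8% of the other genes (12790 of 13780), so this share is close to that of the genome. Positions just beyond called domain edges are argued against for most of the 116 genes without a peak, which lay a median of 113.6 kb from one. At the median, upregulated genes without a peak lay farther from peaks by 0.18 on the log10 scale (permutation test, p = 0.0053). Without the 3R run the difference was 0.17 (permutation test, p = 0.012). These tests were not matched on chromosome arm, and they treat the genes of the other runs as independent. They compare medians, so they do not exclude such positions for a minority of genes, of which the nearest, CG3556, lay 1404 bp from a peak. With gene spans extended by 2000 bp, 17 of 131 upregulated and 1351 of 13780 other genes met a peak, against 15 and 990 without. Weak H3K27me3 that the peak list records only in part stays open. Of 131 upregulated genes, 12 overlapped only peaks with a −log10 q-value under 10, against 516 of 13780 others (odds ratio 2.59, 1.29 to 4.74; Fisher's exact test, p = 0.0042). Length- and arm-matched sets held 6.30 such genes on average (ratio 1.91, permutation p = 0.040). These counts follow from those for any peak and for stronger peaks, which had been seen when the test was chosen, so they do not decide it, and they leave the 116 genes without a peak. A response to H3K27M that does not pass through loss of H3K27me3 at the gene itself was not tested.

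Upregulated genes came in runs, and the one on 3R is the most unusual. From Leash to mAcon2 (3R 10885540 to 11139742, 254.2 kb), 14 of the 15 annotated genes were listed, 8 protein-coding and 6 long non-coding RNA genes out of the 11 on the whole list; the exception was Ak3, which lies inside Leash. From CG6621 on, 13 consecutive annotated genes were listed, against a longest run of at most 4 in 10000 random sets (permutation p = 1e-04, the smallest they can give). A shared called H3K27me3 domain is argued against, because 0% of the 23 run genes overlapped a peak (upper limit 14.8%, which treats them as independent). The nearest peak was 210.9 kb from the 3R region but 2990 bp from the run of CG11594 and Gr64a. H3K27me3 below the peak threshold stays open here too. Double counting of reads from overlapping genes is argued against as the whole cause, since without the 7 genes that overlap another listed gene the neighbouring pairs stayed at 9.20 times the mean of random sets. A linked difference in copy number or strain background on 3R, a chromatin domain that responds as a unit, and other causes cannot be told apart here. The lists hold no DNA coverage or expression level, and the random sets keep no natural grouping of genes along an arm. The run of 13 consecutive genes is a candidate for a check in the read data.

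Germline genes were enriched in the upregulated list. Loss of H3K27me3 from peaks is argued against for the 5 listed germline genes themselves, since 0% of them overlapped a peak in control discs. Having no peak was common, at 92.8% of the genes not listed as upregulated. Among the piRNA pathway genes picked later, rhi was covered over 48.0%, while del, qin, BoYb and SoYb had no peak. H3K27me3 below the peak threshold stays open. Gonad tissue carried along in the dissection of H3K27M discs cannot be told apart from expression in disc cells. None of the fixed testis genes was listed (0% of 14), and 11 of the 16 germline genes, among them vas, aub and osk, were not listed either. The upregulated list did hold other genes known for expression in testis, among them kmg, fan, blanks, Tssk, ACXD, eIF4E3 and Rpt6R, and SdhCL and mAcon2 of the 3R run, which were picked after the list was seen and were not tested. Without the share of such genes among all genes, the genes picked here cannot be weighed against the fixed lists. No fixed list was made for the ovary, so the testis genes do not show that any gonad tissue would be male. A list without levels also does not show how far abundant germ cell transcripts fell short of the level their share would need.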
